A study of Caenorhabditis elegans with 4 samples.

How the data were processed

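Embryos of the C. elegans strain OP75 were studied by chromatin immunoprecipitation with sequencing (ChIP-seq). The strain carries an integrated transgene that encodes the transcription factor ELT-3 fused to enhanced green fluorescent protein (GFP). Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and the fusion protein was collected with an antibody against GFP. Input DNA was set aside from 10% of each lysate. The titles of the 4 samples name 2 ChIP and 2 input libraries, and these titles set the groups. The description fields of the labels differ in part from the titles, since they call the ChIP libraries input DNA and give the antibody for the input libraries. The files were assigned to the samples titled ChIP.

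The authors deposited 3 peak lists and no signal track or read count was used here. One list belongs to each ChIP sample and 1 combined list belongs to the series. Per the file headers, the coordinates are on WormBase WS180, and the source column of each list names PeakSeq as the peak caller. The aligner, the caller's settings, the threshold and the way the combined list was made are not given in the sources used here. The only measurement per peak is a number the files name qValue, a q-value as the authors deposited it, which reads as a p-value between 0 and 1.

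The deposited q-value was tested against what PeakSeq computes, a one-sided binomial test of ChIP tags against scaled control tags. A tail of a binomial distribution with probability 0.5 takes only particular values, so a deposited number can be looked up among them. Totals of up to 3000 tags were searched for every value, and totals of up to 20000 for the 1 value then left. With a relative tolerance of 1e-11, 100.0% of the peaks in each of the 3 lists matched exactly 1 pair of a ChIP tag number and a control tag number. On simulated data the lookup returned the right pair for 100% of 4263 values, and matched 0.0235% of the same values after adjustment by rank. The deposited numbers are therefore treated as unadjusted tail probabilities, and are called peak probabilities here. The files state no tag numbers, so every tag number and tag ratio below was derived in this way and rests on that reading. The depth of each library is unknown. The control numbers are already scaled to the ChIP library, so the 95% exact binomial (Clopper-Pearson) intervals of the tag ratio cover counting error only and take the scaled control as if it were counted. Tags are reads without molecular identifiers, and peaks of more tags have narrower intervals.

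The design was fixed before the data were examined. Peaks of the 2 ChIP lists were called shared when they overlapped by at least 1 bp. Random expectation came from 1000 placements of each peak within its own chromosome, whose extent was taken as the highest peak end in any list, so 0.001 is the smallest p these placements can give. Correlations across peaks used 100000 permutations, two-sided, with 1e-05 as the smallest p. Differences between shared and single-replicate peaks used permutation tests with 100000 resamples and Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 measures. Shares have 95% Wilson intervals. The analyses by rank of X, by the central part of each chromosome, by peak spacing and by recovered tags, tag ratios included, were added after the data were seen, as was the share on X of shared peaks. Alternatives were a reciprocal overlap of 50%, midpoints within 100 bp, the better-scoring 50% of each list, lists of equal length, each replicate list alone, peaks of 50 bp or more, and the replicate 1 list without its first-ranked peak. The split of ChIP tags between the replicate lists was compared with 100000 random binomial splits of the same totals, kept above the calling limits, with the share of replicate 2 fitted. With simulated independent libraries 6.67% of 60 such tests fell under 0.05.

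After the lists were seen, the central share of autosomes and X was also compared by Fisher's exact test. Gene assignment, the 14 gene lists fixed in advance, gene families and the GATA motif were not analysed, because no WS180 annotation or sequence was used here. Coordinates were not moved between builds. The rule fixed in advance for this case names positions in place of genes, namely the 20 best-scoring combined peaks that overlap a peak in both replicates. Other positions named below were chosen after their values were seen. The overlap, correlation and dispersion code was tested on simulated data. It found 100% of 1938 shifted copies of peaks and called 0% of 2001 unmatched peaks shared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.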

Results

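The binding of ELT-3 to the genome was mapped in C. elegans embryos by ChIP-seq. ELT-3 is a GATA-type zinc finger transcription factor of the worm epidermis, and the OP75 strain expresses it with a GFP tag from an integrated transgene, beside its own gene. Embryos came from a mixed population of males and hermaphrodites. There were 2 ChIP libraries and 2 input libraries. The input libraries have no peak list of their own and are taken here as the source of the control behind each list. The labels do not say whether the 2 ChIP samples came from separate cultures, so p-values here measure only the spread between peaks of these lists. With 2 lists there is no SD per peak, and intervals cover counting error.

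The replicate 1 list held 1667 peaks over 561581 bp, the replicate 2 list 3939 peaks over 1252225 bp and the combined list 3936 peaks over 1242763 bp. The median peak was 286 bp wide in replicate 1 and 270.0 bp wide in replicate 2. The peaks of replicate 1 together held 121448 ChIP tags against 43864 scaled control tags, and those of replicate 2 held 335455 against 121129. In replicate 1 a single peak, at I 15063998 to 15067638, supplied 8659 of the ChIP tags (7.13%) and 6435 of the control tags. The median peak held 57 ChIP tags in replicate 1 and 71 in replicate 2, and the fewest were 19 in both lists. The median tag ratio was 3.20 in replicate 1, 2.84 in replicate 2 and 2.84 in the combined list. The largest peak probability was 0.000205 in replicate 1 and 0.000321 in the other 2 lists. These tag numbers were derived from the deposited q-values, and the total reads per library are unknown.

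Which peaks ranked first by peak probability was the first question. The probability depends on tag numbers as well as on the tag ratio, so this is not an order of binding strength. Of the 20 first-ranked combined peaks found in both replicates, 11 lay on chromosome X, 3 on I, 3 on II and 1 each on III, IV and V. The first was the peak at X 16929321 to 16931884, with 785 ChIP tags against 159 control tags, a ratio of 4.94 (95% interval 4.16 to 5.89). In replicate 1 this peak ranked 9th, spanned 1167 bp in place of 2564 bp, and had a ratio of 5.79 (4.09 to 8.40). The peak at X 8035640 to 8036967 followed, with a ratio of 6.44 (5.12 to 8.18) in the combined list and 6.42 (4.85 to 8.64) in replicate 1. The peak at X 14525335 to 14526578 had a ratio of 7.12 (5.48 to 9.38), and that at X 11093649 to 11094461 a ratio of 7.98 (5.92 to 11). The peaks at X 2996411 to 2997466, X 6296071 to 6296882, X 9465476 to 9466175 and X 13700511 to 13701158 had ratios of 6.38, 6.79, 6.85 and 6.90.

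The highest ratio among these 20 positions was 9.14 (6.47 to 13.3) at I 6843238 to 6843669, a peak of 432 bp with 329 ChIP tags. The peak at II 12942396 to 12942793 came next with 8.96 (5.81 to 14.4). The lowest ratio was 3.01 (2.53 to 3.60) at II 14404852 to 14407314, a peak of 2463 bp. Wide peaks of lower ratio also lay at IV 14032593 to 14034498, with 3.75 (3.15 to 4.49), and at III 5106882 to 5109036, with 3.89 (3.19 to 4.79). The only position on V among the 20 was at V 12553222 to 12553744, with 5.98 (4.26 to 8.57). Replicate 1 gave a higher ratio than the combined list at 10 of the 20 positions. At X 16929321 to 16931884 and X 8035640 to 8036967, given above with both values, the intervals overlapped. The 20 positions were chosen for a peak in both replicates and the lists may share tags, so closeness was partly set in advance. Of the 20 positions, 16 were also within the first 20 ranks of replicate 1, and the lowest replicate 1 rank was 29.

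**Figure D1:**
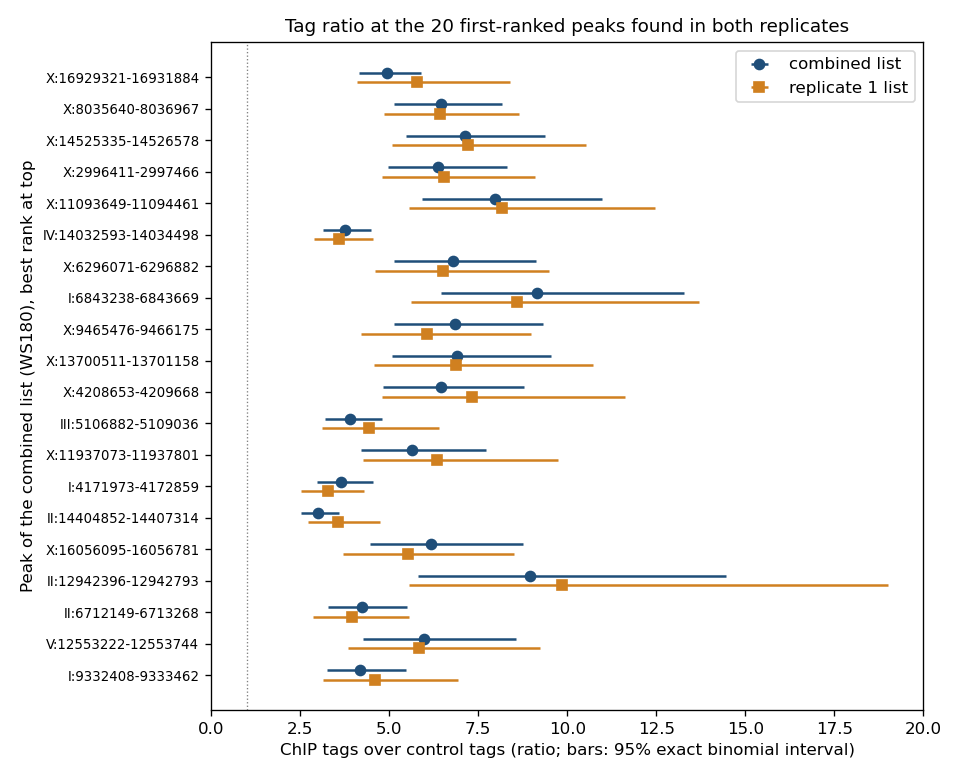
Ratio of ChIP tags to control tags (x axis) at the 20 first-ranked combined peaks found in both replicates (y axis, WS180 positions, best rank at top), for the combined list (circles) and the overlapping replicate 1 peak (squares), with 95% exact binomial intervals. Combined ratios run from 3.01 to 9.14 and replicate 1 ratios from 3.27 to 9.85, all to the right of the dotted line at 1.

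The next comparison asked whether the 2 ChIP samples marked the same regions. Of the 1667 replicate 1 peaks, 1630 (97.8%, Wilson 97 to 98.4) overlapped a replicate 2 peak. Random placement gave a mean of 43.5 and at most 65 (one-sided permutation p = 0.001). In the other direction 1613 of 3939 replicate 2 peaks (40.9%, 39.4 to 42.5) overlapped a replicate 1 peak, against 43.6 by random placement (permutation p = 0.001). With both lists at 1667 peaks, the shares were 79.5% and 78.5%. At 462 pairs of intervals with both ends within 25 bp, the split of ChIP tags between the lists had a dispersion of 0.470, and 100000 random binomial splits of the same totals gave at least 0.699 (random splits, lower-tail p = 1e-05). These splits do not model the choice of intervals with matching ends, and whether the 2 lists are independent stays open. The overlap is therefore not given as agreement of 2 independent samples, and the lists were not averaged.

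**Figure D2:**
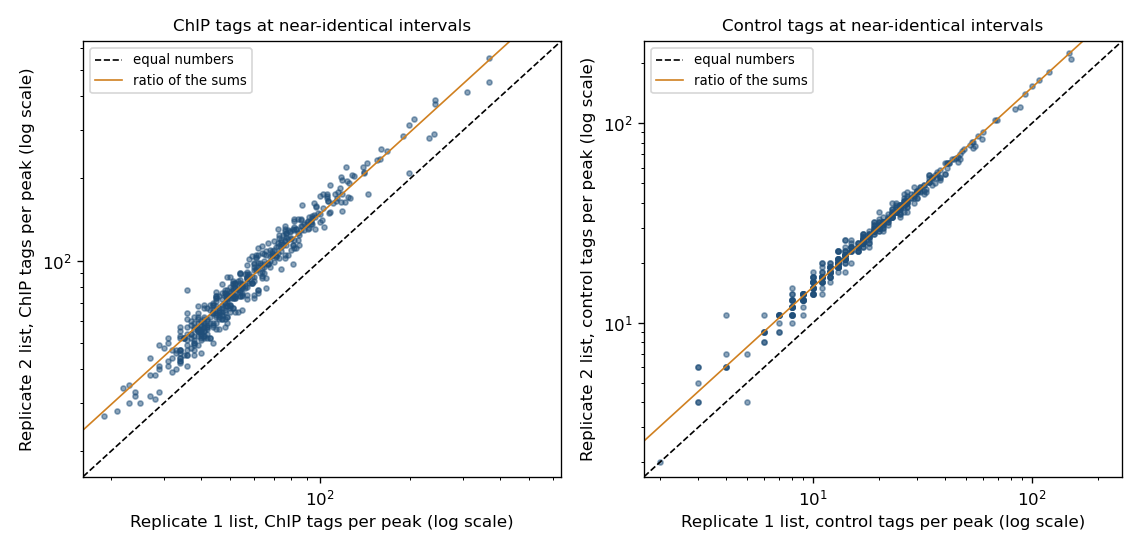
ChIP tags and control tags in replicate 2 peaks (y axes) against replicate 1 peaks (x axes), both on log scales, at 462 pairs of intervals with both ends within 25 bp. Each point is a pair of peaks, the dashed line marks equal numbers and the solid line the ratio of the sums, 1.48 for ChIP and 1.51 for control tags.

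Peaks that ranked high in replicate 2 were mostly found in replicate 1, and those that ranked low mostly were not. The share fell from 97.6% of 788 peaks in the strongest of 5 rank groups to 64.3%, 27.7%, 11% and 4.07% in the next 4. The replicate 1 list was shorter and held fewer tags at matching intervals, so low-ranked peaks could less easily be called there. The lists may also share tags, so the fall was partly set in advance. Across the 1630 overlapping pairs, peak probabilities on the log scale had a Spearman correlation of 0.78 and a Pearson correlation of 0.90 (permutation p = 1e-05 for both). Over the 4 relations computed, the permutation adjusted p of the Spearman correlation was 1e-05, and the Pearson p-values were not adjusted. Without the 2 peaks farthest from the median, Pearson's r was 0.89. ChIP tags per kb had a Spearman correlation of 0.71 and a Pearson correlation of 0.44. The log2 tag ratio gave 0.88 for both. Peak probabilities of the 1462 pairs with a reciprocal overlap of 50% gave 0.81 and 0.95. The control tags behind the 2 lists were nearly proportional, so a correlation above 0 can arise without agreement of the ChIP samples, and peaks are not independent replicates.

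**Figure D3:**
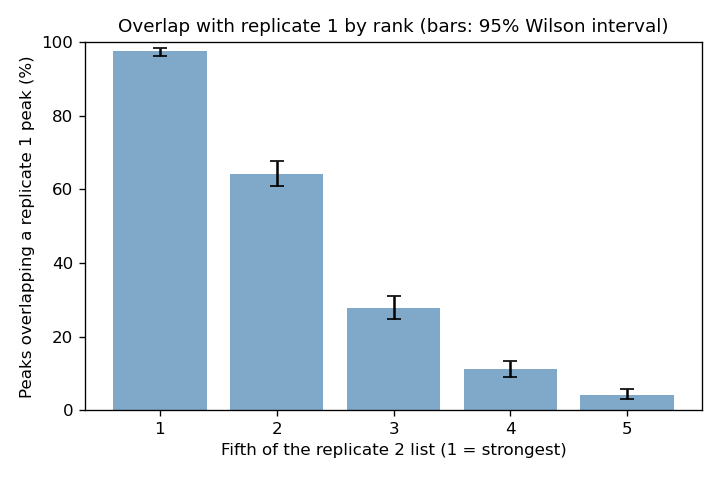
Share of replicate 2 peaks that overlap a replicate 1 peak (y axis, percent) in 5 groups of the replicate 2 list by rank (x axis, 1 = strongest), with 95% Wilson intervals. The share falls from 97.6% in the strongest group to 4.07% in the weakest.

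Shared and single-replicate peaks were then compared. A wider peak is more easily overlapped and one with more tags more easily called, so differences can follow from the definition of shared. In the replicate 2 list the 1613 shared peaks were wider than the 2326 others, with means of 425 ± 282 bp and 244 ± 150 bp (SD over peaks; permutation adjusted p = 1.3e-05). Their tag ratio was higher, with mean log2 values of 1.70 ± 0.41 and 1.49 ± 0.41 (permutation adjusted p = 1.3e-05). Their share on X was 17.6% against 16.6%, a difference that did not pass the test (Fisher's exact test, adjusted p = 0.413). The 37 replicate 1 peaks with no partner in replicate 2 had a median width of 137 bp, against 287 bp in the 1630 others. Their means did not differ past the threshold in any of the 4 measures (permutation and Fisher's exact tests, adjusted p from 0.0513 to 0.828), a result that rested on 1 peak. Without it, shared peaks were on average 119.9 bp wider (permutation adjusted p = 0.00588), had a better peak probability (0.00948) and had a log2 tag ratio that differed by -0.23 (0.00588). The other alternatives changed which peaks were single, so they did not retest the 37. With a reciprocal overlap of 50%, 205 peaks were single, and these 3 measures passed the threshold. With lists of equal length 341 were single, and the log2 ratio difference was -0.03 (permutation adjusted p = 0.269). For peaks of 50 bp or more the single peaks were again another set, and the difference turned to 0.03 (permutation adjusted p = 1.0). The 37 included the first-ranked replicate 1 peak, the peak left out above, at I 15063998 to 15067638, with a peak probability of 9.76e-74 and a ratio of 1.35 (1.3 to 1.39) from 8659 ChIP tags and 6435 control tags. The other 36 began at rank 679 and had a median width of 126.5 bp. The combined list held 2 of the 37, and the first-ranked peak was not one of them.

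The combined list was compared with the list of each sample. Of its 3936 peaks, 1611 (40.9%) overlapped a peak in both replicates, 2265 (57.5%) in replicate 2 only, 1 in replicate 1 only and 59 in neither. It shared 2721 intervals (69.1%) with replicate 2 to the base, and all 2721 had the same peak probability, ChIP tags and control tags in both lists. It shared 8 intervals with replicate 1, none with the same numbers, and replicate 1 had 10 to 63 fewer ChIP tags there. The combined list and the replicate 2 list thus carried the same numbers wherever their intervals were equal. At these intervals the combined list held no more tags than replicate 2 and is no measurement separate from it.

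Peaks lay on all 6 chromosomes. The combined list had 688 peaks on I, 650 on II, 674 on III, 616 on IV, 640 on V and 668 on X. Per Mb of the extent covered by peaks, III had 49.0, I 45.7, II 42.6, X 37.8, IV 35.4 and V 30.6. X held 17% of the peaks (15.8 to 18.2) and 17.7% of the extent, a difference that did not pass an exact binomial test (two-sided p = 0.259). In replicate 1 X held 17.8% (exact p = 0.923). On X the median tag ratio was 2.68 and on I it was 2.59, while II to V had medians from 2.85 to 3.00. Peaks on X and I were also wider, with medians of 293 and 287 bp against 252.5 to 272 bp on the others. Their median control tags per kb were the highest too, 102.6 on X and 114.0 on I, against 89.5 to 93.9 on the others. More control tags let a lower ratio be called, so the ratios are not read as weaker binding on X and I.

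The strongest peaks by probability were also counted on X, after the 20 positions named above had been seen to hold 11. Of the 100 first-ranked combined peaks 27 were on X, against 641 of the other 3836 (16.7%; Fisher's exact test, two-sided p = 0.00995, adjusted p = 0.0202 over 6 rankings). These 100 include the 20 named positions, and of the remaining 80 peaks 16 (20.0%) were on X, so the test largely restates what was seen in the first 20. In replicate 1, 29 of the first 100 were on X against 17% of the rest (Fisher's exact test, adjusted p = 0.0202). All 20 named positions ranked 29th or better in replicate 1, so this test too includes the peaks that prompted it and is no separate support. Ranked by tag ratio, 16 of the first 100 were on X, against 17% of the rest (Fisher's exact test, adjusted p = 0.893), so the excess did not hold under that order. The first 100 by probability had a median of 254.5 ChIP tags and 696 bp, and the first 100 by ratio had 38.5 tags and 155.5 bp.

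On the autosomes peaks were denser toward the chromosome centres. When each extent was divided into 3 equal parts, the central part held 1340 of 3268 autosomal peaks (41.0%), against 33.3% for an even spread (exact binomial test, two-sided p = 5.75e-20). The share was 43.6% on I, 38.9% on II, 38.9% on III, 39.8% on IV and 43.75% on V. In replicate 1 alone it was 40.0% (exact p = 2.07e-07), and ranged from 34.8% on III, close to an even spread, to 45.8% on V. On X the central part held 226 of 668 peaks (33.8%, exact p = 0.806), and the difference from the autosomes passed Fisher's exact test (two-sided p = 0.000603, and 0.0123 in replicate 1). The 1 Mb bin with the most peaks was on I between 7 and 8 Mb, with 79. Clustered peaks are not independent, so these p-values are too small. The even spread takes no account of gene density or of how well reads map along the chromosomes, and the cause was not tested.

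**Figure D4:**
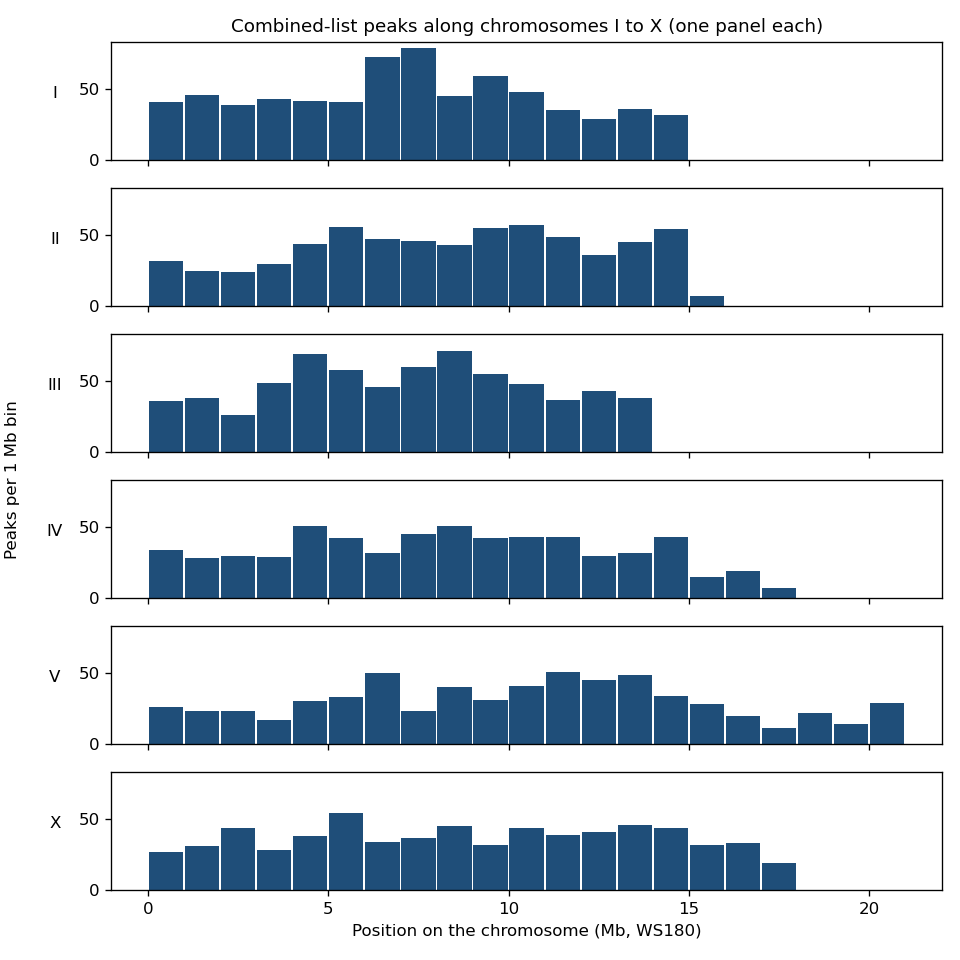
Number of combined-list peaks (y axis) in 1 Mb bins along each chromosome (x axis, Mb, WS180), with 1 panel per chromosome and a last bin that is only partly covered. Chromosome I rises to 79 peaks between 7 and 8 Mb, while the central part of X holds 33.8% of its peaks.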

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

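The tests of X by rank, of tag ratios, of the share of shared peaks on X, of the central part of the autosomes, of tags per kb, of peaks of 50 bp or more and without the first-ranked replicate 1 peak were added after the data were seen. Of the alternatives, 37 kept the direction and the side of the threshold, or stayed within the interval where there was no test. The overlap of the replicates ranged from 79.5% to 98.4% of replicate 1 peaks and from 37.1% to 78.5% of replicate 2 peaks, and stayed above random placement in all 4 alternatives. With a reciprocal overlap of 50%, the share of combined peaks found in both replicates was 37.2% in place of 40.9%. The count of X among the first 100 peaks was 16 by tag ratio, where X fell below its share in the rest, 22 by the lower 95% bound of the ratio and 20 by tags per kb above control, and X held 20.0% of the first 100 without the 20 named positions, which were already seen to hold 11 on X. The cause was not tested. Without replicate 1 or 2, X held 17% to 17.8% of all peaks and 27 to 29 of the first 100, and the central part held 40.0% to 40.8% of autosomal peaks. The list without replicate 1 holds 69.1% of the combined intervals with the same numbers, so it is no separate check. The first 100 of both replicate lists include peaks at all 20 named positions. For the replicate 1 list, these settings changed which peaks were single. With a reciprocal overlap of 50%, 205 peaks were single. The shared minus single differences were 0.877 in minus log10 probability, 85.2 bp in width and -0.22 in log2 ratio, all past the threshold. Equal list lengths, with 341 single peaks, gave 2.35 and 127 bp, also past it, and -0.03 in log2 ratio, not past it. Leaving out the first-ranked replicate 1 peak gave 2.14, 119.9 bp and -0.23, all past it. Differences changed sign, none past the threshold at that setting: the share on X was 1.31 percentage points with equal lengths and 1.58 for peaks of 50 bp or more, against -1.19, and the log2 ratio was 0.0293 for peaks of 50 bp or more, against -0.18. The cause was not tested. No paired analysis was possible because the input libraries have no values in the peak lists. Not run, for want of a WS180 annotation or sequence, were all alternatives for genomic position, gene lists, gene families and the GATA motif. Peaks under 50 bp rested on a median of 29 ChIP tags, against 73 in the others.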

Other observations

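All tests in this part were chosen after the results were seen. Neighbouring peaks were closer than random placement gave. The median gap between neighbouring midpoints was 14209 bp, against 17315 bp on average and at least 16417 bp in 1000 placements (one-sided permutation p = 0.001). Gaps of 2 kb or less made up 12.9%, against 7.73%. The densest 20 kb window, at II 6821905 to 6841445, held 10 peaks, of which 6 were found in both replicates, and random placement gave 6.61 on average and at most 11 (permutation p = 0.002). Windows with 8 peaks lay at I 8974944 to 8986251, II 5319917 to 5339031, III 3862907 to 3879666 and III 4492122 to 4508593. The placements did not keep the higher density of the autosome centres.

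Some peaks were very narrow. In the combined list 188 peaks (4.78%) spanned under 50 bp and 8 spanned 1 bp. Of these 188, 16 (8.51%) were found in both replicates, against 42.6% of the 3748 wider peaks (Fisher's exact test, two-sided p = 4.97e-24). Narrow peaks offer less length to overlap, so this difference can follow from the definition of shared. Their median tag ratio was 4.50 against 2.80, from medians of 29 and 73 ChIP tags. The highest ratio of the combined list was at V 2033287 to 2033307, where 25 ChIP tags stood against 1 control tag, a ratio of 25 with an interval of 4.09 to 1026.

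The 2 combined peaks of lowest tag ratio, 1.43 (1.27 to 1.60) at X 13915732 to 13918484 and 1.46 (1.29 to 1.65) at X 13947251 to 13949615, bounded a stretch of X of 33.9 kb with 3 further peaks, 1 of which held 885 ChIP tags, the most of any combined peak. A candidate explanation is extra DNA copies, as an integrated transgene would bring. All 3 peaks between the outer ones had more control tags per kb (160.0 to 195) than the 95th percentile (147) of 512 other peaks of 500 bp or more, of which the highest had 289.9. A low ratio is called only where control tags are many, and against 37 other wide peaks of no higher ratio the median of the 3 was 1.45 times as high and 1 of the 3 passed the 95th percentile (189), so extra copies and binding without extra DNA cannot be told apart. The elt-3 gene lies on X, but whether this block holds it was not examined on WS180.

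The replicate 2 list may hold the tags of replicate 1, but neither simple case tested met the data. The split of ChIP tags at 462 pairs of intervals with both ends within 25 bp had a dispersion of 0.470, against 0.699 to 1.16 in binomial splits of the same totals above the calling limits, and at 185 pairs with 150 or more tags it was 0.541 against 0.593 to 1.38 (random splits, lower-tail p = 1e-05 for both), but the choice of intervals with matching ends can itself narrow the split and was not modelled, so independent ChIP libraries and shared tags cannot be told apart. With the overall share of tags in place of the fitted one the dispersion was 0.384. Simulated independent libraries gave 0.649 to 1.02. Simulated lists that held all replicate 1 tags gave 0.140 to 0.217, so plain nesting missed it too. In only 324 of the 462 pairs did the replicate 2 interval contain the replicate 1 interval, so this miss does not exclude nesting. Of 1267 replicate 2 peaks containing a replicate 1 peak, 0 had fewer ChIP tags. This count has a simulated value only among the 324, where independent libraries gave 0 to 11. The control tags had 0.0434 of the binomial variance at a ratio of 1.51, but separate control libraries cannot be told apart from 1 shared control, because the depth of the input is unknown and a deep control scaled down also varies less. The combined list had the same ChIP and control tags as replicate 2 at all 2721 intervals equal to the base. A combined list that added separate replicate 1 tags to those of replicate 2 would hold more ChIP tags there. The equal numbers argue against such a list at these intervals. They do not show whether replicate 2 holds the tags of replicate 1, since how the combined list was made is not given. A pooled list and further sequencing of the replicate 1 library were not told apart, and no biological explanation was tested.

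The first-ranked replicate 1 peak, at I 15063998 to 15067638, was missing from the other 2 lists. It had 1767 control tags per kb, against at most 369 and a median of 62.9 among the other replicate 1 peaks of 50 bp or more, and the lowest tag ratio of its list, which is what many DNA copies would give. It lay 70.6 kb beyond the last combined peak on I, toward the chromosome end known to carry the ribosomal RNA gene repeats, although an overlap with them was not examined on WS180. If the control scales by the same 1.51, the replicate 2 list could hold a ratio of up to 1.05 there without a call. A difference in recovery between the samples cannot be told apart from a filter on such regions, because the replicate 2 list gives no value there.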
